A study of Mus musculus with 32 samples.

How the data were processed

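Mouse embryonic stem cells of a C57BL/6 background carrying a knockout of Mettl3 or of Mettl14, and the control cells of each line, were grown with LIF at 1000 U/ml and the inhibitors CHIR99021 at 3 µM and PD0325901 at 1 µM, per the labels. The sample titles call the knockouts CKO, which commonly stands for conditional knockout. They do not say how or how completely the gene was deleted. METTL3 and METTL14 form the core of the enzyme complex that places N6-methyladenosine (m6A) on RNA. RNA carrying m6A was enriched with an antibody and sequenced (MeRIP-seq) from polyadenylated RNA (mRNA) and from chromatin-associated RNA with ribosomal RNA removed (caRNA), with spike-in control RNA of the EpiMark kit added and libraries made with the SMARTer Stranded Total RNA-Seq v2 kit. The series held 32 samples. The 16 immunoprecipitation libraries each came with a peak list and formed 8 groups of 2 replicates, by RNA type, line and genotype. The 16 input samples were not used here.

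The authors deposited 1 strand-specific peak list per immunoprecipitation library, without pooling replicates. The submitters' processing notes name the mm10 genome build, CASAVA, Trimmomatic 0.38, HISAT2 2.1.0 and SAMtools 1.9, with no role or order. The peak caller, its settings and how immunoprecipitation and input were scaled are not given in the sources used here. Each deposited list held 3 kinds of value per peak. The deposited fold enrichment is a ratio of the immunoprecipitation over the background the authors' caller used. The deposited −log10 p and −log10 q are the caller's significance, and the lowest −log10 q of a list lay between 2.00 and 2.02. The deposited summit offset gives the position of highest signal in bases from the peak start. The shortest peak of all lists spanned 150 bp. Fold enrichments are the authors' values per peak and were used to describe, rank and filter peaks within a list. Folds of different lists stand side by side for single genes and for spike-in RNA, as values with no test between lists. Read depth is unknown, so no counting interval could be given, and a missing peak can mean lower methylation, lower RNA abundance or lower depth.

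Peaks on spike-in RNA were set aside before counting. Peaks of the 4 lists of a comparison were merged by strand into regions where they overlapped by at least 1 bp. A region was called lost if it held a peak of both controls and of neither knockout, gained if it held a peak of both knockouts and of neither control, and retained if it held a peak of all 4 libraries. Percent lost refers to regions with a peak in both controls and percent gained to regions with a peak in both knockouts. Genes were called the same way from summits lying in the body of that gene alone. A gene can therefore be retained without any single region found in all 4 libraries, and its fold in each list is that of its best peak there. Gene bodies came from a table of the GRCm38.p6 assembly, the same build as mm10, with 49980 genes, 21900 of them protein-coding. The table gives neither exons nor strand and no genome sequence was used here. The planned shares of summits near the stop codon, in introns or between genes, the GGAC and DRACH motif measures, the exon rule for mRNA and the transcript region classes were therefore not run. In their place stand the shares of summits of protein-coding genes in the last 10% and in the first 10% of the gene body along the strand of the peak, the share outside genes, the covered length and the median peak width, all chosen after the data were seen. The dominant strand of a gene was taken as the strand with the larger summed −log10 p over the 16 lists, also after the data were seen. A strong lost peak adds to the sum of its own strand, and a retained region adds peaks of all 4 libraries of its comparison, which favours the dominant strand for retained regions by construction. Fisher's tests of lost or gained against retained regions by strand were run, but are not used for that reason.

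The 2 libraries per group allow no exact test within a comparison below p = 0.333. Differences were therefore tested over the 4 comparisons together with an exact two-sided permutation test that permuted genotype labels within each comparison. Its smallest possible p is 0.00154. The overlap between lists, as the Jaccard index in bp, was tested one-sided over 81 distinct splits, with a smallest possible p of 0.0123. Benjamini-Hochberg adjustment covered 7 measures, and 6 for each difference between lines or RNA types. Lost genes shared by the lines were tested with Fisher's exact test over genes marked in both controls of both lines. Odds ratios of position were also given within quartiles of control peak strength by the Mantel-Haenszel method. For these quartiles, and for quintiles of strength, the strength of a region was the mean fold percentile of its control peaks. Genes and regions are not replicates, so those tests describe these libraries.

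The 15 gene lists were pluripotency, lineage, m6A machinery, Polycomb, chromatin regulators, ribosomal proteins, mitochondrially encoded genes, nuclear-encoded oxidative phosphorylation, nuclear long noncoding RNA, immediate early genes, Wnt and TGF-β signalling, cell cycle, replication-dependent histones, feeder fibroblast markers, and a list of genes of the 2-cell-like state and trophoblast. They held 427 entries, 426 of them distinct genes, and all were matched, 35 through older symbols. Each list was tested with Fisher's exact test for lost genes against all genes marked in both controls, adjusted over the lists of a comparison. Tests of gained genes, of the percent of regions lost against 10000 random gene sets with matching numbers of regions per gene (a gene-set permutation test) and of last-10% odds ratios were chosen after the data were seen. The random gene sets were not matched by peak strength. Groups, region and gene calls, the gene lists, the tests of peak number, overlap, lost lists and shared lost genes, the rule for named genes and the alternatives for region and gene calls, peak number and overlap were fixed before the data were examined. The rule named, per comparison, the 8 lost and the 8 gained genes with the highest mean fold percentile within the lists holding them, the 4 retained genes highest in the controls, Mettl3 and Mettl14, every member of the m6A machinery and pluripotency lists, and up to 4 members of any other list standing apart, passing over predicted genes and genes overlapping others. Some genes the rule names are not reported here.

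The alternatives were peaks with −log10 q of at least 5, the 10000 strongest peaks per library, an overlap of at least 50% of the shorter peak, summits within 100 nt, summits given to every gene they lie in, a replicate block, each RNA type alone, each library left out in turn, the last quintile of the gene and the dominant strand alone. Replicate numbers are the submitters' and nothing in the labels pairs a control with a knockout. The scripts were tested on simulated peak lists. In regions simulated from each comparison all true lost genes with a peak in both simulated controls were recovered (100%). The way the lists were simulated fixed this value in advance, so it checks the code alone. False calls made up 3.72% in mRNA Mettl3, 2.50% in mRNA Mettl14, 2.59% in caRNA Mettl3 and 1.68% in caRNA Mettl14. These shares rest on a set rate of missing peaks and do not estimate the error in the real lists. The permutation test gave p under 0.05 in 7% of 200 simulations with no effect and in 93% with an effect of 2 replicate SDs. The list test, simulated on mRNA Mettl3 with 8306 genes and 200 sets of 25, called 3.5% of sets with no shift and 100% with 40% of members lost. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.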

Results

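N6-methyladenosine (m6A), the most abundant internal modification of messenger RNA, was mapped by immunoprecipitation and sequencing in mouse embryonic stem cells. The cells were labelled as knockouts (CKO) of Mettl3, the catalytic subunit of the methyltransferase, or of Mettl14, its partner subunit. The control cells of each line were mapped as well. How complete the deletion was is not known here, so a retained peak is not shown to be independent of the enzyme. Polyadenylated RNA (mRNA) and chromatin-associated RNA (caRNA) were profiled, which gave 4 comparisons of 2 knockout with 2 control libraries. In mRNA the lists held 22165 and 22592 peaks in the Mettl3 controls and 22521 and 23239 in the knockouts. The Mettl14 lists held 16537 and 17738 peaks in the controls and 23380 and 22654 in the knockouts. In caRNA the Mettl3 lists held 37955 and 40090 control and 45241 and 41162 knockout peaks, and the Mettl14 lists 42514 and 41315 control and 38272 and 39385 knockout peaks. Regions and genes were called lost when both controls and neither knockout held a peak, gained when both knockouts and neither control did, and retained when all 4 libraries did. Read depth is unknown, and peak presence does not measure a methylation level or an RNA level. Nothing in the labels says that replicates came from separate cultures. The exact permutation tests of genotype labels therefore rest on the spread between these libraries, which may be technical. Fisher's exact and gene-set permutation tests take genes or regions as units and measure no spread between libraries.

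The knocked-out genes themselves carried few peaks. Mettl14 (chromosome 3, 123368295 to 123385990, mm10) lost its peak in caRNA of the Mettl14 knockout, where the controls had fold enrichments of 3.82 and 2.82. In caRNA of the Mettl3 line the same gene gained a peak, with fold enrichments of 5.53 and 5.33 in the knockouts. In mRNA of the Mettl14 line it had peaks in both controls (1.69 and 3.07) and in 1 knockout library (2.30), and in mRNA of the Mettl3 line no peak. Mettl3 (chromosome 14, 52294841 to 52308741) was retained in caRNA of both lines, with fold enrichments of 4.16 and 6.82 in controls and 4.26 and 4.64 in knockouts of the Mettl3 line. In caRNA of the Mettl14 line they were 5.82 and 5.83 in controls and 6.27 and 5.17 in knockouts. There the gene was retained, but 1 of its 3 control regions was lost and none held a peak of all 4 libraries. In mRNA, Mettl3 had a peak in 1 Mettl3 knockout library (3.40) and none in the Mettl14 line. Peaks in a target gene neither measure its expression nor check the genotype.

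In mRNA of the Mettl3 knockout, the comparison asked which m6A regions depend on METTL3. Of the pluripotency genes, Nanog and Pou5f1, core transcription factors of the stem cell state, lost their peaks, which had been weak in the controls (fold enrichments of 1.69 and 2.32 for Nanog, 1.56 and 1.92 for Pou5f1). The planned test of pluripotency genes did not pass, with 2 of 23 marked genes lost (Fisher's exact adjusted p = 0.517). In the test of regions, chosen after the data were seen, 15 of 63 pluripotency regions were lost (23.8%). The median in matched random gene sets was 9.23% (gene-set permutation adjusted p = 0.0240). With the 10000 strongest peaks per library the direction reversed, with 8.33% of pluripotency regions lost (gene-set permutation p = 0.718). Sall4 lost 4 of 5 regions and Tbx3 lost 3 of 5, and both kept at least 1 retained region. Among ribosomal protein genes 4 of 16 marked in the controls were lost, Rpl24, Rpl38 and Rpl4 among them, which did not pass (Fisher's exact adjusted p = 0.0705). Of the m6A machinery, Mettl16, another RNA methyltransferase, was lost (5.05 and 2.80), as was Igf2bp1, an m6A reader (1.62 and 1.39), whereas Mettl5, an 18S ribosomal RNA methyltransferase, was gained (5.47 and 6.14). The machinery list did not pass, with 2 of 20 marked genes lost (Fisher's exact adjusted p = 0.517).

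The lost genes with the highest enrichment were Rpl4, Gpr135, an orphan receptor, Dner, a ligand of Notch, Fuca1, a lysosomal fucosidase, Tmem156, Fhl4, Osr2, a zinc-finger transcription factor, and Crnkl1, a splicing factor, with control fold enrichments between 7.22 and 9.50. The strongest lost peak of Gpr135 (chromosome 12, 72069325 to 72069785) had folds of 9.15 and 7.98. That of Rpl4 (chromosome 9, 64178289 to 64178448; 9.32 and 9.47) lay on the minus strand, the strand of this gene with the smaller summed peak significance. Gained genes were led by Fhod1, a formin (chromosome 8, 105338888 to 105339096; 10.3 and 13.9), and included Dnajb2, a co-chaperone, Mmachc, which processes vitamin B12, Gngt2, Med27, a Mediator subunit, Exosc8, an exosome subunit, Pnp2 and Frrs1l, with folds between 8.27 and 13.9. Pik3ca, the catalytic subunit of a lipid kinase, led the retained genes (35.2 and 29.6 in the controls), followed by Mfap3l, Manea and Zhx1.

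Of 18841 control regions in this comparison, 1914 were lost (10.2%), and of 18830 knockout regions 1874 were gained (9.95%), whereas 15128 control regions (80.3%) were found in all 4 libraries. A single knockout library lacked 14.9% ± 0.454 (SD, n = 2) of control regions. At gene level 376 were lost, 435 gained and 7573 retained. Lost and gained regions together came to 3788, against 595 and 642 for the other splits of the same 4 libraries, and the matching gene counts were 811 against 130 and 154. With 1 library left out, so that its partner alone decided presence, genes lost came to 566 to 623 whichever library was left out, genes gained to 704 without control 2 and 748 without knockout 1, regions lost to 16.3%, 15.5% and 15.3% without control 1, control 2 and knockout 2, and regions gained to 15.2%, 17.1% and 15.3% without control 2, knockout 1 and knockout 2.

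**Figure D1:**
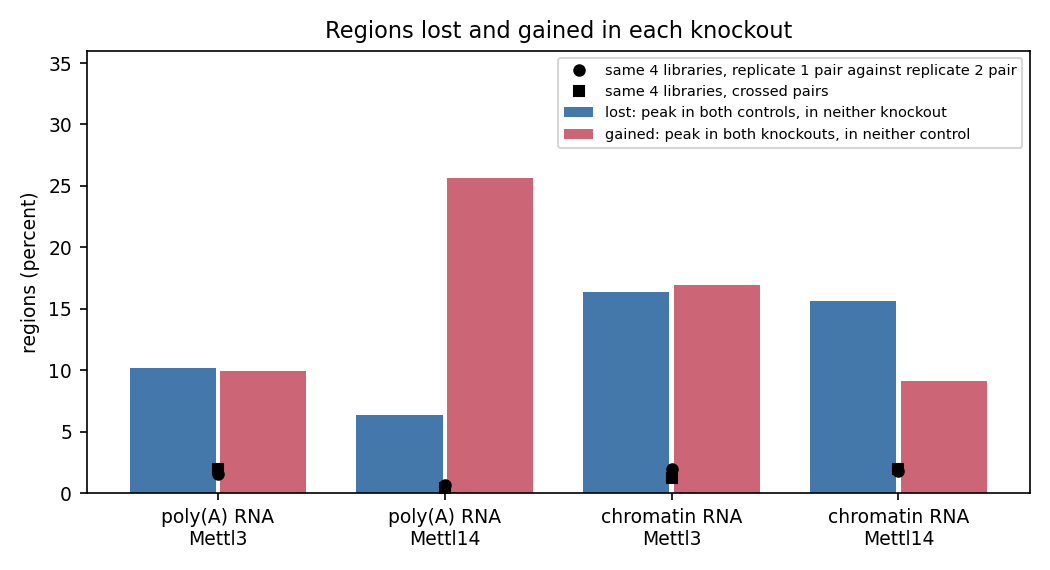
Percent of control regions lost and of knockout regions gained in each comparison (bars, from 0), with the share of regions found in both libraries of a mixed pair and in neither of the other pair (points) for the other splits of the same 4 libraries. Gained regions stood at 25.6% in mRNA of the Mettl14 knockout and lost regions there at 6.33%.

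**Figure D2:**
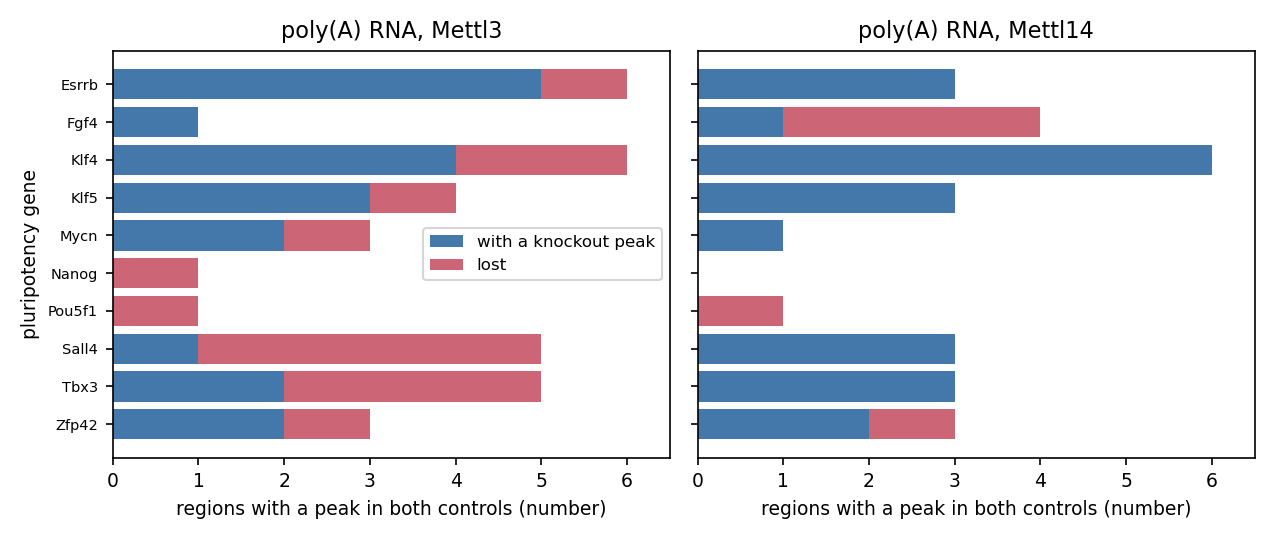
Number of regions with a peak in both controls of each pluripotency gene with a lost region in either line, in mRNA of the Mettl3 line (left) and of the Mettl14 line (right), split into those with a knockout peak and those lost. Sall4 and Tbx3 lost 4 and 3 of 5 regions in the Mettl3 line, and Fgf4 lost 3 of 4 in the Mettl14 line.

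In mRNA of the Mettl14 knockout gains outnumbered losses. Strongly gained genes were Ltb4r1, a leukotriene receptor (chromosome 14, 55768230 to 55768482; 16.7 and 14.6), Egr1, an immediate early transcription factor (14.9 and 16.1), and Irs1, an insulin receptor substrate (17.1 and 14.04). Dpysl3, Bdkrb2, a bradykinin receptor, Pcgf6, a Polycomb subunit, and Cln3 followed, and these genes had folds between 10.03 and 17.1. Lost genes were Pgam1, a glycolytic enzyme (chromosome 19, 41912037 to 41912292; 12.9 and 14.3), the ribosomal protein genes Rpl3 and Rpl21, Hnrnpdl, an RNA-binding protein, Npm1, a nucleolar chaperone, Bsg and Fer, a tyrosine kinase, with folds between 7.32 and 14.3. The peaks of Pgam1, Hnrnpdl, Bsg and Rpl21 lay on the minor strand of the gene, and those of Npm1, Rpl3 and Fer on the strand with the larger sum, although Npm1 and Rpl3 are known to be transcribed from the minus strand and these peaks were on the plus strand. Over the whole comparison 31.3% of lost regions (257 of 820) were on the minor strand, against 13.6% of gained (560 of 4107) and 5.31% of retained regions (592 of 11158). The dominant strand was set from the same peaks, to which a retained region gives more libraries than a lost or gained one, so their difference has no neutral value to test against. Whether minor-strand peaks come from antisense RNA or from incomplete strand separation was not determined, so the loss of such a peak is not shown to be a loss from the transcript of the named gene. The second spike-in RNA held peaks on both strands in every library, with mean folds of 1.60 on plus and 5.46 on minus in these controls. Peaks on both strands of a single added RNA thus occur in these lists, but this does not decide the question for any gene. Ovol2, Acvr2a, an activin receptor, and Syt14 were the most enriched of the retained genes (20.1 to 21.2 in the controls).

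Of 5 ribosomal protein genes marked in this comparison 4 were lost (Rpl13, Rpl3 and Rps6 among them; Fisher's exact adjusted p = 1.06e-05), as were 5 of 5 regions (gene-set permutation adjusted p = 0.00280). Of the 5 lost regions 4 were on the minor strand, those of Rps6, Rpl13 and Rpl4 among them, and the other was the plus-strand region of Rpl3, so none is shown to lie on the sense strand. With the dominant strand alone 1 ribosomal gene was lost (Fisher's exact p = 0.0144), while without control 1 the count was 8. Of the pluripotency genes Pou5f1 was lost (5.59 and 6.26), on its minor strand, whereas its lost peak in the Mettl3 line was on the other strand, and Tdgf1, a Nodal co-receptor, was gained (1.88 and 1.9). Of 22 marked pluripotency genes 1 was lost (Fisher's exact adjusted p = 1), and of 18 marked m6A machinery genes 0 (adjusted p = 1). Feeder fibroblast markers gained 3 of 9 (Acta2, Col1a1 and Col6a1; Fisher's exact adjusted p = 0.440).

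Of 14104 control regions 893 were lost (6.33%), and of 20263 knockout regions 5196 were gained (25.6%), with 12886 control regions (91.4%) in all 4 libraries. Genes numbered 139 lost, 1244 gained and 6823 retained. A single control library lacked 31.0% ± 2.70 (SD, n = 2) of knockout regions, and a single knockout library 7.48% ± 0.266 of control regions. Lost and gained regions came to 6089, against 192 and 223 for the other splits, and genes to 1383 against 49 and 61. With the 10000 strongest peaks per library, which gives lists of equal length, 10.1% were lost and 12.3% gained, with 277 genes lost and 372 gained. With shared regions defined by summits within 100 nt, 12.7% were lost, and without control 1 the losses were 10.5% of regions and 242 genes.

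In caRNA of the Mettl3 knockout Gbx2, a homeobox gene of the pluripotency list, lost all 3 of its regions (10.3 and 12.5 for the strongest, chromosome 1, 89928310 to 89929190), and Myc lost its peak (2.90 and 3.54). The other named lost genes were Slc25a10, a mitochondrial dicarboxylate carrier (chromosome 11, 120498256 to 120498744; 11.9 and 15.7), Mrpl50, a mitochondrial ribosomal protein, Bloc1s3, Dapp1, Tcf19, Sox13, a transcription factor, and Dnal4, with folds between 8.84 and 15.7 over the 8 genes. Gained genes were Tspan1, a tetraspanin (10.4 and 9.95), Mrpl47, Ptprt, a receptor phosphatase whose gained peak lay on its minor strand, Mgll, a lipase, Plekha3, Slc7a11, the cystine transporter, Iqca1l and Eaf2, with folds between 6.37 and 10.4. Usp35, Arl15, Elk4 and Gmeb2 led the retained genes (27.8 to 42.5).

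Regions of 3 gene lists were lost less often than those of matched random gene sets in this comparison. The sets were matched by regions per gene and not by peak strength, which also went with loss. Replication-dependent histone genes lost 0 of 31 regions, nuclear-encoded oxidative phosphorylation genes 1 of 44 (2.27%) and ribosomal protein genes 2 of 58 (3.45%), against random medians of 16.1%, 15.0% and 17.2% (gene-set permutation adjusted p = 0.0290 for each). With the 10000 strongest peaks per library histone genes lost 0% (gene-set permutation p = 0.152) and ribosomal protein genes 0% (p = 0.0634). Feeder fibroblast markers gained 4 of 11 genes (Acta2, Col6a1, Mmp2 and Thy1; Fisher's exact adjusted p = 0.0232), and 1 with the 10000 strongest peaks (p = 0.428). Of the pluripotency list 2 of 29 marked genes were lost (Fisher's exact adjusted p = 1) and of the m6A machinery 0 of 23 (adjusted p = 1).

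Over this comparison 5303 of 32347 control regions were lost (16.4%) and 5756 of 33980 knockout regions gained (16.9%), with 23821 (73.6%) in all 4 libraries. A single knockout library lacked 21.4% ± 2.11 (SD, n = 2) of control regions. There were 620 genes lost, 515 gained and 9323 retained. Lost and gained regions came to 11059 against 988 and 1172 for the other splits, and genes to 1135 against 91 and 139. With the 10000 strongest peaks 30.4% were lost and 1004 genes. Genes lost came to 974 without knockout 1, genes gained to 813 without control 2 and 924 without knockout 2, and regions gained to 27.4% without knockout 2, while oxidative phosphorylation regions lost came to 4.55% to 7.84% with any library left out and ribosomal protein regions to 7.35% and 7.46% without control 1 and control 2.

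In caRNA of the Mettl14 knockout Lin28a, an RNA-binding regulator of let-7 microRNA, lost its peaks (chromosome 4, 134004895 to 134005164; 7.99 and 8.07), and Stat3, the effector of LIF signalling, gained one (3.95 and 3.22). Besides Lin28a, the named lost genes were Abitram (chromosome 4, 56802358 to 56803390; 15.2 and 13.2), Grhpr, a glyoxylate reductase, the ferritin pseudogene Ftl1-ps1, Itpka, an inositol phosphate kinase, Clcn1, a chloride channel, Cdipt and Cyp27b1, a vitamin D hydroxylase, with folds between 6.38 and 15.2. Gained genes were Serpini1, a serine protease inhibitor (10.98 and 12.004), Bola2, Zfp987, Dnmt3l, a cofactor of DNA methylation (8.02 and 8.81), Capn2, Myo6, Tnfrsf11b and Dtna, with folds between 6.27 and 12.004. Chd7, a chromatin remodeller, Usp35, Ankrd24 and Wdr81 led the retained genes (27.2 to 33.5). Of the m6A machinery, Mettl14 and the m6A reader Igf2bp3 were lost, 2 of 24 marked genes (Fisher's exact adjusted p = 1), and of the pluripotency list 1 of 26 (adjusted p = 1).

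In this comparison 3 gene lists held more gained genes than the background. Histone genes gained 4 of 13 (H1f4, H1f5, H2ac8 and H2bc6; Fisher's exact adjusted p = 0.00507), ribosomal protein genes 4 of 11 (Rpl13, Rpl19 and Rpl5 among them; adjusted p = 0.00493) and mitochondrially encoded genes 3 of 8 (COX2, ND1 and ND4L; adjusted p = 0.00900). Both caRNA controls of the Mettl14 line marked 7 histone and 7 ribosomal protein genes, against 19 and 33 in the Mettl3 line. For these 2 lists the control lines thus differed more than knockout and control did. Mitochondrially encoded genes marked in both controls numbered 5 and 3. With the 10000 strongest peaks 0 mitochondrially encoded genes were gained (Fisher's exact p = 1), and no ribosomal protein gene was marked in the knockouts. Among oxidative phosphorylation genes Cyc1, Ndufb5, Ndufv1 and Sdhd were lost, 4 of 15, which did not pass (Fisher's exact adjusted p = 0.134). Regions lost numbered 5568 of 35554 (15.7%), regions gained 2840 of 30997 (9.16%), and 25731 control regions (72.4%) were in all 4 libraries, with 595 genes lost, 325 gained and 9109 retained. A single knockout library lacked 21.6% ± 0.949 (SD, n = 2) of control regions. Lost and gained regions came to 8408 against 957 and 962 for the other splits, and genes to 920 against 88 and 103. Regions gained were 14.7% with the 10000 strongest peaks, 14.4% with summits within 100 nt, and 15.8% and 14.6% without knockout 1 and knockout 2. Genes gained came to 537, 581 and 538 without control 1, knockout 1 and knockout 2, and genes lost to 897 and 927 without control 2 and knockout 2.

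Across the 30 pluripotency genes, 18 were retained in all 4 comparisons (among them Dppa2, Dppa4, Esrrb, Fgf4, Il6st, Klf2, Klf4, Klf5, Lifr, Mycn, Nr0b1, Nr5a2, Sall4, Tbx3, Tet2, Tfcp2l1 and Zfp42). Gbx2, Myc, Prdm14 and Tdgf1 were retained in 3, Nanog, Pou5f1 and Utf1 in 2, and Dppa3, Dppa5a, Lin28a and Stat3 in 1. Sox2 lies within the longer noncoding gene Sox2ot, so its summits were assigned to neither. Of the 25 m6A machinery genes, 13 were retained in all 4 comparisons (Alkbh5, Cbll1, Fto, Igf2bp2, Rbm15, Rbm15b, Virma, Wtap, Ythdc1, Ythdf1, Ythdf2, Ythdf3 and Zc3h13), among them the methyltransferase cofactors Wtap and Virma and both known demethylases, Fto and Alkbh5. Hnrnpa2b1, Hnrnpc, Igf2bp1, Mettl16 and Pcif1 were retained in 3, Fmr1, Mettl3, Mettl5 and Zcchc4 in 2, Igf2bp3 in 1, and Mettl14 and Ythdc2 in 0. These are calls of genes and not of regions. Igf2bp1 in mRNA Mettl14, for example, lost its 1 control region and gained another, and so counted as retained.

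The 3′ ends of protein-coding genes held a smaller share of summits in the knockouts. The share in the last 10% of the gene body differed by −3.87, −3.44, −5.43 and −2.39 percentage points in mRNA Mettl3, mRNA Mettl14, caRNA Mettl3 and caRNA Mettl14, and over the 4 comparisons it fell by 3.78 points (exact permutation p = 0.00154, the smallest possible; adjusted p = 0.00360). The group means went from 32.1% ± 0.335 to 28.2% ± 0.238, from 37.6% ± 0.896 to 34.2% ± 0.266, from 22.6% ± 0.488 to 17.2% ± 0.0450 and from 21.7% ± 0.262 to 19.3% ± 0.0407 (SD, n = 2 each). A smaller share need not mean fewer regions there. Regions of the last 10% with a peak in both knockouts numbered 4645, 5665, 4837 and 4813, in the same order. Those with a peak in both controls numbered 5231, 4555, 6294 and 6071, so the number was higher in the mRNA Mettl14 knockout. The share in the first 10% rose by 1.66 points (2.33, 2.59, 1.19 and 0.520 points; exact permutation p = 0.00154, adjusted p = 0.00360). Within mRNA alone the first-10% difference was 2.46 points and within caRNA alone 0.856 points (permutation p = 0.0556 for each, the smallest possible).

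**Figure D3:**
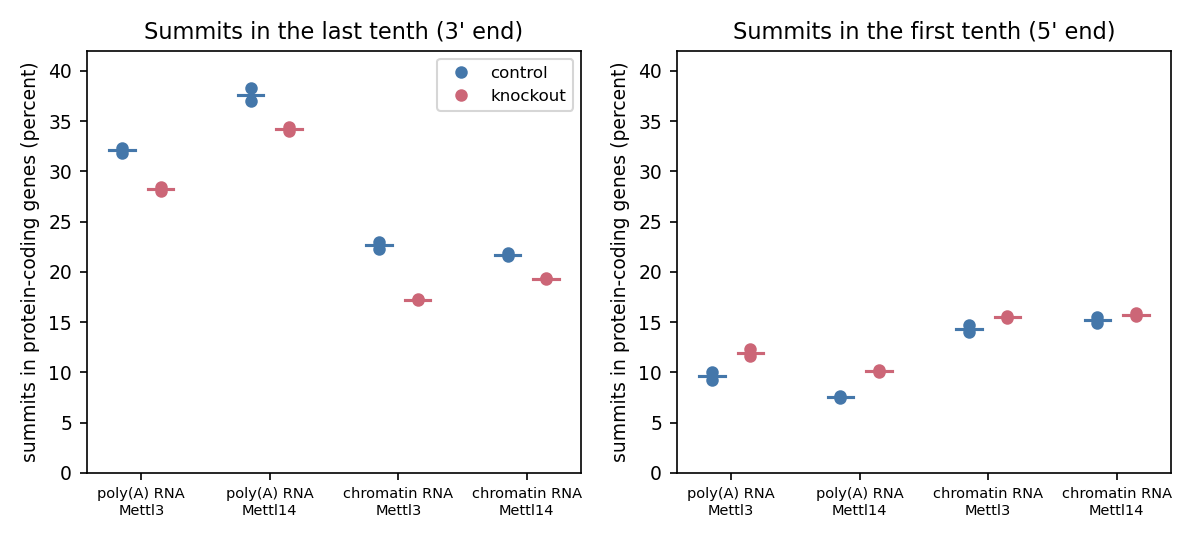
Percent of summits in protein-coding genes that lay in the last 10% (left) and in the first 10% (right) of the gene body, with 1 point per library and a line at each group mean. In each comparison the knockout mean was lower in the last 10%, such as 28.2% against 32.1% in mRNA Mettl3, and higher in the first 10%.

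Region loss was also uneven along genes. In caRNA of the Mettl3 knockout 22.3% of control regions in the last 10% were lost against 12.9% elsewhere in the gene (odds ratio 1.93; within strength quartiles 2.27, 95% interval 2.11 to 2.45), and in mRNA of that line 11.5% against 8.41% (odds ratio 1.41; 1.45, 1.30 to 1.62). In mRNA of the Mettl14 knockout the direction was opposite, with 4.65% against 8.15% (odds ratio 0.550; 0.544 within quartiles), and in caRNA of that line 14.7% and 14.2% were lost (odds ratio 1.04, Fisher's exact p = 0.338; 1.34, 1.23 to 1.46 within quartiles). Gained regions were rarer in the last 10% in all 4 comparisons, with odds ratios of 0.429 in mRNA Mettl3, 0.453 in mRNA Mettl14, 0.432 in caRNA Mettl3 and 0.340 in caRNA Mettl14. Weak control regions were lost more often than strong ones, from 17.3% in the weakest quintile to 1.16% in the strongest in mRNA Mettl3, from 10.1% to 3.41% in mRNA Mettl14, from 17.6% to 2.60% in caRNA Mettl3, where the next weakest quintile lost 27.1%, and from 30.8% to 0.238% in caRNA Mettl14, whose next weakest quintile lost 32.7%.

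**Figure D4:**
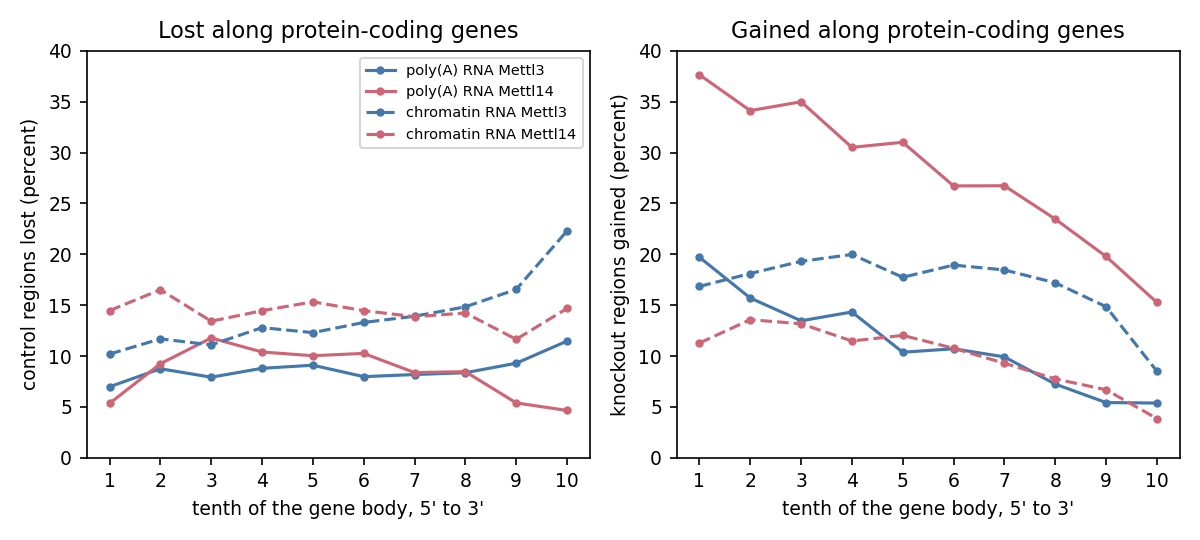
Percent of control regions lost (left) and of knockout regions gained (right) in each 10% step along the body of protein-coding genes, from 5′ to 3′ along the strand of the peak, with 1 line per comparison. In the last 10% 22.3% of control regions were lost in caRNA Mettl3 and 4.65% in mRNA Mettl14.

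Peaks were narrower in the knockouts, with a median width that fell by 23.5 bp over the 4 comparisons (exact permutation p = 0.00154, adjusted p = 0.00360). With the 10000 strongest peaks per library it fell by 80 bp (exact permutation p = 0.0463). Median widths of the full lists went from 277 to 249 bp in mRNA Mettl3, from 311.5 to 305 bp in mRNA Mettl14, from 269 to 239.5 bp in caRNA Mettl3 and from 310 to 280 bp in caRNA Mettl14. Peak number did not pass, at 1868.5 more per knockout library (exact permutation p = 0.137, adjusted p = 0.192), nor did the share of summits outside genes (0.100 points, p = 0.816) or the covered length (−0.708 Mb, p = 0.304, both from the exact permutation test). Overlap in bp between control and knockout lists was lower than between replicates by a mean Jaccard difference of −0.147 (exact permutation p = 0.0123, the smallest possible; adjusted p = 0.0216). The between and within values were 0.644 and 0.748 in mRNA Mettl3, 0.606 and 0.795 in mRNA Mettl14, 0.522 and 0.697 in caRNA Mettl3 and 0.632 and 0.753 in caRNA Mettl14.

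Regions outside annotated genes were lost at 18.1%, 24.8% and 23.4% in mRNA Mettl3, caRNA Mettl3 and caRNA Mettl14, against 9.67%, 15.8% and 14.6% of the other regions, and at 3.12% against 6.53% in mRNA Mettl14. In mRNA Mettl14 42.9% of the knockout regions outside genes were gained, against 23.9% of the other knockout regions. The minor strand held 10.5% of lost, 8.60% of gained and 4.24% of retained regions in mRNA Mettl3, 13.96%, 6.44% and 4.48% in caRNA Mettl3, and 14.8%, 5.39% and 6.02% in caRNA Mettl14, shares to which the same limit applies.

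The lines shared more lost genes than independence gives, in a test that did not match genes by peak strength or by number of regions. In mRNA 197 genes were lost in the Mettl3 and 51 in the Mettl14 knockout among 6407 genes marked in all controls, and 11 were lost in both against 1.57 if independent (Fisher's exact p = 2.85e-07). They included Actb, Bbs4, Coq10b, Cox7b, Fads2, Nono, Pou5f1, Proca1, Rpl21 and Vav1, of which Actb and Pou5f1 had their control peaks on different strands in the 2 lines. With the dominant strand alone 5 genes were shared (Fisher's exact p = 0.00259), with the 10000 strongest peaks 5 (p = 0.225), and without control 1 of the Mettl3 or of the Mettl14 line 18 and 17. In caRNA 65 genes were lost in both among 8985 (428 and 241 lost, 11.5 if independent; Fisher's exact p = 3.67e-32), among them Itpka, Clcn1, Morn4, Cdkn2c, a cell cycle inhibitor, Wasf1 and Pex5, a peroxisomal import receptor, chosen after their values were seen. Without knockout 2 of the Mettl14 line 100 were shared. At the level of regions 22 of 11168 were lost in both lines in mRNA (7.27 if independent) and 455 of 22197 in caRNA (146 if independent). The odds ratios were 3.69 and 5.74. Within strength strata they fell to 2.51 (95% interval 1.54 to 4.09) and 4.21 (3.67 to 4.83).

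Differences between the lines in the knockout effect, averaged over both RNA types, did not pass the exact permutation test for any of 6 measures (p between 0.344 and 0.840), among them peak number (−943.5 peaks, Mettl14 minus Mettl3) and the last-10% share (1.73 points). The average for peak number hides differences of opposite sign, since the knockouts differed from their controls by 5879.5 peaks in mRNA Mettl14 and 501.5 in mRNA Mettl3, but by −3086 in caRNA Mettl14 and 4179 in caRNA Mettl3. The lines were not tested against each other within an RNA type. Between RNA types the knockout effect on covered length differed by −3.32 Mb, from −2.37 Mb in caRNA and 0.951 Mb in mRNA (exact permutation p = 0.0185, adjusted p = 0.111).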

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

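The tests of 3′ end regions, of the 3′ share and of shared function over chromatin-associated RNA regions were chosen after the results were seen. For the test by peak strength, the fold percentiles of gained regions, though not their −log10 p percentiles, had been seen before its prediction was written.

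The highest percent of gained regions among the 4 comparisons was in mRNA of the Mettl14 knockout (25.6%, 5196 regions), such as those of Irs1 and Egr1, in lists that were longer than those of the controls, whereas with the 10000 strongest peaks per library it was in caRNA Mettl3 (24.0%), with 12.3% in mRNA Mettl14. Among mRNA lists it was these controls that stood apart, with 16537 and 17738 peaks and median −log10 q of 27.5 and 31.9. The other mRNA lists held 22165 to 23380 peaks, with medians of 34.8 to 42.8. Nuclear RNA carried into the polyadenylated fraction stays open, although gained regions met caRNA peaks of both controls less often than retained regions of the same strength (−14.1 points, SE 1.01; 64.3% against 90.3% before matching; 15.0% against 6.15% outside genes), which met the bound written beforehand against it, but retained regions have mRNA control peaks by definition and gained regions none, so that bound was wrong. Weak peaks passing the threshold in longer lists cannot be told apart from new sites, because gained regions had a median strength percentile of 27.7 in the knockout lists (69.6 for retained regions), between the bounds set beforehand. For shared loss of methyltransferase function, the odds ratio among regions without mRNA control peaks was 0.210 (95% interval 0.173 to 0.254; 124 regions gained in both lines of 8597), which met the bound written beforehand against it, but every region of that set held a knockout peak by construction, which lowers the ratio, so a value below 1 decides nothing. Over 6568 caRNA regions without mRNA control peaks it was 2.40 (1.80 to 3.21; 61 in both lines against 30.0 if independent), consistent with shared sites, as differences in RNA abundance among regions could also be.

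Regions at the 3′ ends of genes were lost more often than others in the Mettl3 knockout. Within quartiles of control strength the odds ratio stayed at 1.45 in mRNA and 2.27 in caRNA, so differences in fold between these quartiles do not account for it. Strength here is the fold percentile, whereas the lists end at a −log10 q. The quartiles thus do not hold the distance from the threshold equal, and weak peaks dropping below it stay open as a cause. A loss of METTL3-dependent sites near 3′ ends remains a hypothesis, and a change in the coverage of 3′ ends or in read depth may give the same and was not tested.

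The 3′ share was lower also in mRNA of the Mettl14 knockout, although its 3′ regions were lost less often than others. Regions kept from the controls held 0.971 points more in the last 10% than all control regions (39.8% against 38.8%), which follows from that lower loss by arithmetic and so decides nothing. Gained regions held 22.4%, against 39.8% of the regions kept, so among regions the lower share lay with those gained. Whether these were newly called peaks or new sites stays open.

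The following pairs moved in opposite directions in every library, and these differences were not tested as pairs. Peak number differed by 4179 per library in caRNA Mettl3, −3086 in caRNA Mettl14 and 5879.5 in mRNA Mettl14. The share of summits outside genes differed by −1.08 points in mRNA Mettl3, 3.41 in mRNA Mettl14 and −2.04 in caRNA Mettl14. Covered length differed by −0.749 Mb in mRNA Mettl3, 2.65 Mb in mRNA Mettl14 and −3.33 Mb in caRNA Mettl14. The difference of −3.32 Mb between the knockout effects on covered length in caRNA (−2.37 Mb) and mRNA (0.951 Mb) passed its own exact permutation test before adjustment (p = 0.0185, adjusted p = 0.111).

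Peaks on the spike-in RNA, outside the comparisons, had a mean fold enrichment in the knockout lists above that in the control lists in 7 of the 9 cases with peaks in all 4 libraries. These are the authors' values per list, whose scaling is not given, so no change was tested or read from them. Which of the 2 spike-in RNAs carries m6A is not given in the sources used here, so these folds cannot be assigned to m6A enrichment or to background. For the second spike-in on the minus strand the means were 7.50 ± 0.876 against 5.11 ± 0.880 in mRNA Mettl3, 8.495 ± 1.65 against 5.46 ± 0.293 in mRNA Mettl14, 13.9 ± 3.71 against 5.62 ± 0.119 in caRNA Mettl14 and 9.67 ± 0.218 against 8.41 ± 0.220 in caRNA Mettl3 (SD, n = 2 each). On the plus strand they were 2.33 ± 0.142 against 1.60 ± 0.266 in mRNA Mettl14 and 3.48 ± 0.0437 against 2.82 ± 0.108 in caRNA Mettl14, and for the first spike-in 1.67 ± 0.155 against 1.47 ± 0.122 in caRNA Mettl3. In the other 2 cases, the second spike-in on the plus strand, the knockout mean was lower, at 1.40 ± 0.0236 against 2.25 ± 0.447 in mRNA Mettl3 and 2.70 ± 0.519 against 2.74 ± 0.283 in caRNA Mettl3. The first spike-in had peaks in the controls alone on the minus strand in mRNA Mettl14 (6.04 and 5.71) and on the plus strand in mRNA Mettl3 (1.25 and 1.47), and in the knockouts alone on the minus strand in caRNA Mettl3 (2.87, the higher of 2 peaks, and 2.98).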

How the results depend on the processing

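Settings for percent lost and gained, genes lost and gained (except the dominant strand), peak number and overlap were planned, and all others given here were chosen after the data were seen. Of 504 values under alternatives, 411 stayed within limits that differed between kinds of value. Tests had to keep their direction and side of the threshold, and shares had to move by less than the replicate spread. Overlap was judged by the spread between comparisons, and gene counts by a fixed ratio to the main count. By that ratio 1698 gained genes against 1244 in mRNA Mettl14 counted as kept. Of the other values 83 moved further, 5 reversed, 4 fell short of the threshold and 1 passed it newly. Where no construction is named the cause was not tested. Lists of equal length, the 10000 strongest peaks, gave lost and gained regions of 12.2% and 12.1% in mRNA Mettl3, 10.1% and 12.3% in mRNA Mettl14, 30.4% and 24.0% in caRNA Mettl3 and 14.7% and 14.7% in caRNA Mettl14, with 277 genes lost and 372 gained in mRNA Mettl14 and 1004 lost in caRNA Mettl3. That setting also gave a covered length difference of −0.828 Mb (exact permutation p = 0.0494), a width difference of −80 bp (exact permutation p = 0.0463), line differences of −0.673 points outside genes (exact permutation p = 0.221), 5.05 points in the last 10% (p = 0.238), −1.94 points in the first 10% (p = 0.211), 1.10 Mb covered (p = 0.179) and 87.5 bp of width (p = 0.258), 5 shared lost genes in mRNA (p = 0.225), 1 feeder marker (p = 0.428) and 0 mitochondrially encoded genes gained (p = 1). Under it 8.33% of pluripotency regions (gene-set permutation p = 0.718), 0% of histone regions (p = 0.152) and 0% of ribosomal protein regions in caRNA Mettl3 (p = 0.0634) were lost, and gained ribosomal protein genes in caRNA Mettl14 got no value, as no member was marked in its knockouts. Summits within 100 nt gave 13.3% and 13.9%, 12.7% and 29.0%, 19.7% and 21.7%, and 19.5% and 14.4%, and −log10 q of at least 5 gave 6.01% lost in mRNA Mettl14.

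Within mRNA and caRNA alone the differences were 3190.5 and 546.5 peaks, 2.46 and 0.856 points in the first 10%, 1.17 and −0.965 points outside genes, 0.951 and −2.37 Mb covered, and −17.25 and −29.75 bp of width. The dominant strand alone left 1 ribosomal gene lost in mRNA Mettl14 (p = 0.0144) and 5 shared lost genes in mRNA (p = 0.00259), and moved the last-10% difference to −4.18 and the first-10% difference to 1.89 points (exact permutation p = 0.00154 for each). With 1 library left out its partner alone decides presence, which raises lost and gained counts by construction. Regions lost then ranged over 14.6% to 16.3%, 7.28% to 10.5%, 19.9% to 22.9% and 20.9% to 22.3% in mRNA Mettl3, mRNA Mettl14, caRNA Mettl3 and caRNA Mettl14, and regions gained over 14.4% to 17.1%, 29.1% to 32.9%, 22.0% to 27.4% and 12.5% to 15.8%. Genes lost ranged over 566 to 623, 183 to 242, 779 to 974 and 824 to 927, and genes gained over 619 to 748, 1453 to 1698, 665 to 924 and 456 to 581. Shared lost genes ranged over 12 to 18 in mRNA and 77 to 100 in caRNA, and ribosomal genes lost in mRNA Mettl14 over 4 to 8. The line difference in peak number ranged from −1963.25 to 76.25, turning sign without knockout 1 of caRNA Mettl3 (exact permutation p = 0.972), and the caRNA Mettl14 odds ratio of loss in the last 10% from 0.999, without control 2 (p = 0.986), to 1.07. The last-10% difference stayed between −3.94 and −3.62 points and the width difference between −24 and −23 bp.

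Swapping labels only within a replicate number, which nothing says pairs the libraries, gave exact permutation p-values of 0.227 for peak number, 0.00781 for the last 10%, the first 10% and width, 0.914 outside genes and 0.406 for covered length. For line differences they were 0.750, 0.563, 0.898, 0.469, 0.695 and 0.680 in the order peak number, last 10%, first 10%, outside genes, covered length and width. Correlations of rank differences between libraries of equal number were −0.00111, 0.0109, −0.00186 and 0.00489. Alternatives that needed exons, stop codons or sequence were not run. Depth is unknown, so equal list length stands in for equal depth only in part.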

Other observations

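The tests of gained genes and of regions per list given here were chosen after the data were seen. A gene counts as lost here only when neither knockout holds a peak in it, so a gene not lost can still lose regions. Of chromatin regulators, 0 of 43, 35, 44 and 43 marked genes were lost in mRNA Mettl3, mRNA Mettl14, caRNA Mettl3 and caRNA Mettl14, which did not pass (lowest Fisher's exact adjusted p = 0.517). Of their regions 13 of 178, 12 of 135, 32 of 274 and 25 of 323 were lost, or 7.30%, 8.89%, 11.7% and 7.74%, against random medians of 8.82%, 8.46%, 13.4% and 13.2% (lowest gene-set permutation adjusted p = 0.111, in caRNA Mettl14). Wnt and TGF-β pathway genes lost 0 of 30, 27, 27 and 29 (lowest Fisher's exact adjusted p = 0.878), and in mRNA Mettl3 1 of 68 of their regions was lost against a random median of 9.33% (gene-set permutation adjusted p = 0.0862). Polycomb genes lost 0 of 28, 22 and 29 genes in the first 3 comparisons and Pcgf5, 1 of 25, in caRNA Mettl14 (lowest Fisher's exact adjusted p = 0.878). Of their regions 12 of 59 (20.3%) were lost in mRNA Mettl3, against a random median of 9.26% (gene-set permutation adjusted p = 0.0862). In mRNA Mettl14, caRNA Mettl3 and caRNA Mettl14 the shares of 2.56%, 13.3% and 13.3% lay below random medians of 5.41%, 14.6% and 14.1%. Nuclear long noncoding RNAs lost 0 of 14, 9, 14 and 13 (Fisher's exact adjusted p = 1), and genes of the 2-cell-like state and trophoblast 0 of 6, 9, 6 and 2 (Fisher's exact adjusted p = 1).

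Lineage genes were lost singly, Krt18 and Otx2 in mRNA Mettl3 (2 of 13), Gsc in mRNA Mettl14 (1 of 14), Gata4 in caRNA Mettl3 (1 of 14) and Gsc in caRNA Mettl14 (1 of 8), with a lowest Fisher's exact adjusted p of 0.517. Fgf5, Foxa2, Gata4, Sox17 and T, markers of the epiblast and of early mesoderm and endoderm, were gained in mRNA Mettl14, 5 of 19 marked in the knockouts (Fisher's exact adjusted p = 0.440). Gata4, Lefty2 and T were gained in mRNA Mettl3, 3 of 14 (Fisher's exact adjusted p = 0.450). In caRNA Mettl14 Dnmt3b and Krt8 were gained, 2 of 9 (Fisher's exact adjusted p = 0.127), and in caRNA Mettl3 0 of 11. Immediate early genes lost 0 of 25 and 22 in mRNA, Dusp4 and Dusp6, phosphatases of the ERK pathway, in caRNA Mettl3 (2 of 25) and 0 of 22 in caRNA Mettl14 (lowest Fisher's exact adjusted p = 0.878), and Egr1 and Fos were gained in mRNA Mettl14, 2 of 25 (Fisher's exact adjusted p = 0.654). Cell cycle genes lost Aurka and Mad2l1 in mRNA Mettl3 (2 of 19), Trp53 in mRNA Mettl14 (1 of 14) and 0 of 24 in caRNA of each line (lowest Fisher's exact adjusted p = 0.517). Peaks with an overlapping peak on the opposite strand made up 9.56% ± 0.00135 of each mRNA Mettl14 knockout list against 5.80% ± 0.773 in the controls, whereas the knockout share was lower in the other comparisons, at 5.83% ± 0.0407 against 6.71% ± 0.0517 in mRNA Mettl3, 5.07% ± 0.478 against 8.36% ± 0.0155 in caRNA Mettl3 and 6.39% ± 0.166 against 8.14% ± 0.100 in caRNA Mettl14 (SD, n = 2), not tested.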
